A study of Mus musculus with 21 samples.

How the data were processed

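Hepatocytes were perfused from livers of 90-day-old mice, and chromatin immunoprecipitation with sequencing (ChIP-seq) was used to map where proteins or a histone mark sit on the genome. Mice with floxed Arid1a alleles and no Cre are called WT here, and mice with the same alleles plus Cre recombinase under the albumin promoter, which removes Arid1a in the liver, are called KO. ARID1A is a subunit of the SWI/SNF chromatin remodelling complex, and C/EBPα is a transcription factor of differentiated hepatocytes. The antibodies were against C/EBPα (2 WT and 2 KO libraries), against dimethylated lysine 4 of histone H3 (H3K4me2, a mark of promoters and enhancers; 3 WT and 3 KO libraries) and against the V5 tag in 1 library from mice carrying V5-tagged Arid1a. Of the 21 samples, these 11 each have 1 list of peaks, and the remaining 10 are input samples that were not used here. Per the labels, the C/EBPα and V5 libraries and the H3K4me2 libraries were made with different kits and sequenced on different instruments, so values are never compared between targets except as overlaps.

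The submitters' processing notes name the genome build mm10 and the tools Bowtie2 2.2.3, Picard, MACS2 2.0.10.20131216 and HOMER, without their roles or order. The deposited C/EBPα and V5 lists give the chromosome, start, end and name of each peak and nothing on its strength. Their peak names are numbered with gaps: the peaks present come to between 40.0% and 40.1% of the highest number in each of the 5 lists, so about the same share of an earlier list was kept each time. How that share was picked is not stated in the sources used here. In the H3K4me2 lists no number is missing, and the authors' peak caller gave each broad peak a fold over the local background of its library, a score, and the −log10 p and −log10 q of the peak. The deposited score equals the whole part of 10 times the −log10 q. The lowest −log10 q in the 6 lists lies between 1.00 and 1.02. The deposited fold, score and −log10 values depend on the depth of their own library, so the main tests used them only to rank peaks within a list. The stricter peak threshold is an exception: it cut all 6 H3K4me2 lists at the same pooled median −log10 q. Its values can therefore reflect depth, as can the medians of −log10 q set side by side to describe lists.

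The number of sequencing reads is not given in the sources used here, so the depth of each library is unknown, and the number of peaks in a list is not a measure of it. A feature missing from a list means that no peak was called or kept there, not that nothing was bound. The exact binomial (Clopper-Pearson) 95% intervals given with shares cover counting of peaks or regions only. Tests on regions or genes compare the lists at hand, since regions and genes are not independent replicates. Only the tests on values per library measure the spread between samples. Whether Arid1a was removed cannot be checked in these peak lists, so the genotypes are as labelled.

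Genes and their coordinates came from the RefSeq annotation of GRCm38, the assembly that mm10 names, with 21883 protein-coding genes. The annotation used here has no strand. The planned promoter window was therefore replaced by a window of 1 kb on each side of both annotated ends of a protein-coding gene, called a gene end below, which takes in the 3′ end of a gene as well as its start. Coordinates are mm10 and count from 1. Of the 330 genes in 20 fixed lists (hepatocyte functions, growth and stress genes, chromatin and clock genes, and markers of other cell types), 329 matched the annotation.

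C/EBPα peaks of the 4 lists were merged where they shared at least 1 bp. A region is called lost when both WT lists have a peak in it and neither KO list does, gained for the reverse, and kept when all 4 lists have a peak. The same rule was applied to gene ends, and to H3K4me2 with all 3 lists of a genotype, over gene ends and over 1-kb bins of the genome, where a bin counts as marked in a list when at least 500 bp of it lie in peaks. Strength within a list is the percentile of peak width for C/EBPα and V5, which have no score, and of −log10 q for H3K4me2. Group means were compared with exact permutation tests over libraries. With 2 against 2 libraries the smallest possible p is 0.333 and with 3 against 3 it is 0.1, so no test of this kind can go below 0.05. Counts of lost and gained features were set beside the same counts for the other splits of the libraries. Fixed gene lists were tested with Fisher's exact test against the other genes that could have been lost or gained, with Benjamini-Hochberg adjustment over the 20 lists and a threshold of 0.05. Odds ratios within 5 strata of strength were pooled by the Mantel-Haenszel method. ARID1A overlaps were set beside 100 seeded shuffles of the V5 peaks within chromosomes. Every test is two-sided.

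Genes are named by a fixed rule. It takes the members of the fixed lists with a lost or gained gene end, the 5 lost and 5 gained gene ends with the highest mean percentile in each comparison, the 10 widest V5 peaks, at most 3 members of each list with a V5 peak at a gene end, and always Arid1a, Cebpa and Alb. For V5 the rule asked for peak scores, and width took their place. Genes chosen after their values were seen are marked as such. The lists, tests and naming rule were set before the data were examined, except for the window around both gene ends and the use of width as strength, which the files made necessary, and for the tests and settings that the text names as added or chosen after the data or the result were seen. The alternatives tried were a stricter peak threshold, lists of equal length, each library left out in turn, same-numbered libraries taken as pairs, other overlaps, other windows around gene ends, merged regions in place of bins, and several settings added after seeing the data, which the closing section names. A search for the C/EBP motif was planned and not run, because no genome sequence was used here. The code was tested on simulated peak lists: all 100 planted losses and all 100 planted gains were recovered among 4888 simulated regions for C/EBPα and among 4959 for H3K4me2. Every other simulated region stood in every list, and merged regions took the place of bins for H3K4me2. The simulation therefore checks the code and not how the rule deals with missed peaks. In separate random draws, a planted log2 odds ratio of 2 was fitted as 1.99 and 2.02. Python 3.11.15 was used with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1, statsmodels 0.14.6 and matplotlib 3.10.9.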

Results

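The data are 11 peak lists from adult mouse hepatocytes. They cover C/EBPα in 2 WT and 2 KO libraries, H3K4me2 in 3 WT and 3 KO libraries, and V5-tagged ARID1A in 1 library without a replicate. The C/EBPα lists held 17733 and 23646 peaks in WT and 16178 and 17781 in KO, and the ARID1A list held 5726. The H3K4me2 lists held 34849, 61246 and 49802 peaks in WT and 24908, 54544 and 175797 in KO. Arid1a itself had an H3K4me2 peak at a gene end in all 6 lists and no C/EBPα peak at a gene end in any of the 4. Alb, which encodes albumin, and Cebpa, which encodes C/EBPα, had gene-end peaks in all 4 C/EBPα lists and all 6 H3K4me2 lists.

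The first comparison asks where C/EBPα sits with and without ARID1A. C/EBPα peaks lay at gene ends in 13.7% (95% interval 13.2 to 14.2) and 14.2% (13.8 to 14.7) of the WT lists and in 19.9% (19.2 to 20.5) and 18.8% (18.3 to 19.4) of the KO lists. The KO mean of 19.4% ± 0.721 (SD, n = 2) was 5.40 percentage points above the WT mean of 14.0% ± 0.355 (SD, n = 2), a gap several times the spread within either genotype. Peaks outside genes made up 33.6% ± 0.390 of the KO lists and 38.1% ± 0.421 of the WT lists (SD, n = 2). The exact permutation p was 0.333 for both shares, the smallest that 2 against 2 libraries allow. Peak numbers overlapped between genotypes, with a log2 ratio of KO to WT of -0.29 (exact permutation p = 0.667).

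**Figure D1:**
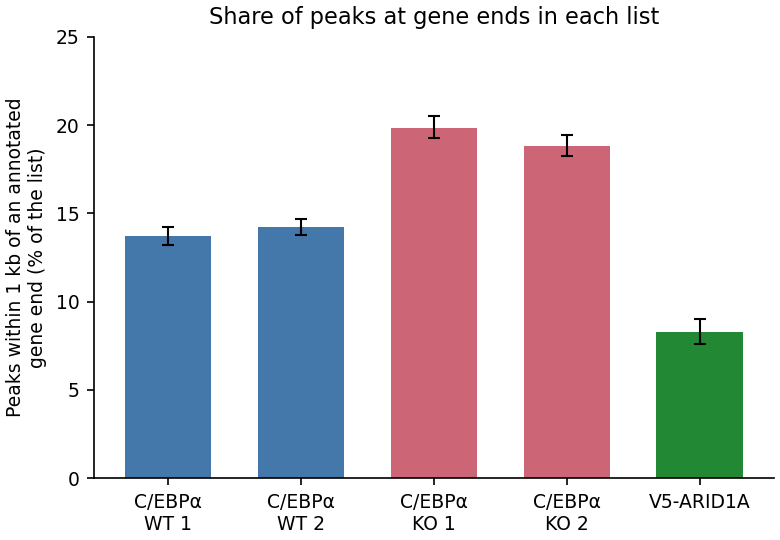
Share of peaks within 1 kb of an annotated gene end, in percent of each list, for the 4 C/EBPα lists and the ARID1A list; error bars are exact 95% binomial intervals over peaks. The KO lists stand at 19.9% and 18.8%, both above the WT lists at 13.7% and 14.2%.

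The 4 C/EBPα lists merged into 27244 regions, of which 11664 (42.8%) were kept, with a peak in every list. Lost regions numbered 3189, or 19.3% of the 16529 with a peak in both WT lists, and gained regions 749, or 5.27% of the 14222 with a peak in both KO lists. The lost region with the highest width percentile lay 6817 bp from an end of Cisd1, which encodes a mitochondrial outer membrane protein (chromosome 10, 71322945 to 71324410, mean width percentile 99.9). Another lay 6122 bp from Sash1 (chromosome 10, 8951090 to 8952371), where H3K4me2 had a peak in 2 WT lists and no KO list. The highest gained region was at an end of Cat, the gene of the peroxide-degrading enzyme catalase (chromosome 2, 103484941 to 103486312, percentile 99.7), and another lay 14673 bp from Igfbp2, which encodes a circulating binding protein of insulin-like growth factors (chromosome 1, 72809327 to 72810288). These 4 regions were chosen after their values were seen, as the highest of their class or near a gene of known function.

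Genotype parted the C/EBPα lists more than the other splits did, but 3 splits are too few for a share under 0.05. The split by genotype gave 3938 regions present in both lists of one side and absent from the other, against 1082 and 561 for the other 2 ways of pairing the 4 lists. Of the merged regions with a peak in at least 1 of 2 replicates, 67.3% had a peak in both for WT and 72.9% for KO. For 2 lists of different genotype it was between 56.7% and 59.6%. The number of lost regions over gained ones, 4.26, depended on which peaks were counted: with the 16178 widest peaks of every list, 1916 regions were lost and 1549 gained, and with only the peaks at least as wide as the pooled median, 1216 were lost. Leaving out WT list 1 gave 7067 lost regions, and leaving out WT list 2, KO list 1 or KO list 2 gave 2363, 1988 or 1495 gained ones.

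Lost and gained regions differed in where they lay. Only 5.36% (4.61 to 6.20) of lost regions were at a gene end, against 17.7% (17.0 to 18.4) of kept regions and 38.3% (34.8 to 41.9) of gained regions. Outside genes lay 48.4% of lost, 34.9% of kept and 24.6% of gained regions. Regions at gene ends were lost in 171 of 2366 cases (7.23%) and other regions in 3018 of 14163 (21.3%), a log2 odds ratio of -1.79 (-2.03 to -1.56, Fisher's exact p = 1.51e-69). Regions at gene ends were gained in 287 of 2841 cases (10.1%) and other regions in 462 of 11381 (4.06%), a log2 odds ratio of 1.41 (1.19 to 1.63, Fisher's exact p = 1.02e-32). Regions seen in a single list showed the same contrast, with 5.35% and 8.76% at gene ends for WT lists 1 and 2 and 32.7% and 23.5% for KO lists 1 and 2. Narrow peaks were lost most: from the narrowest to the widest of 5 strata of WT peak width, 37.6%, 23.8%, 16.3%, 11.3% and 7.50% of regions were lost. Loss was spread over the genome, from 16.8% on chromosome 15 to 22.4% on chromosome X, the extremes of 20 chromosomes.

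**Figure D2:**
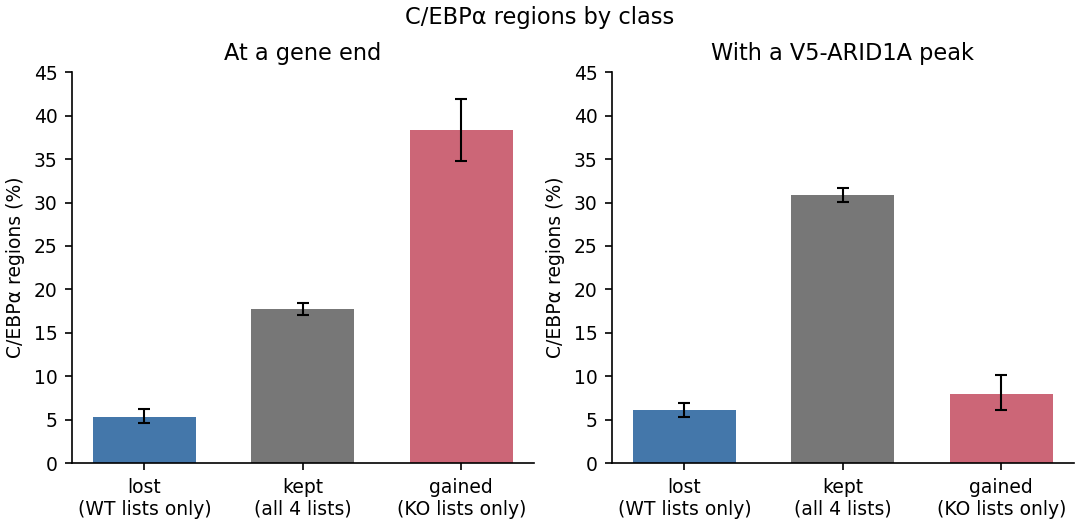
Percent of C/EBPα regions at a gene end (left) and with an overlapping ARID1A peak (right), for the 3189 lost, 11664 kept and 749 gained regions; error bars are exact 95% binomial intervals over regions. Gene ends hold 5.36%, 17.7% and 38.3% of the 3 classes, and ARID1A peaks 6.08%, 30.9% and 8.01%.

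Counted by gene within 1 kb of gene ends, more genes gained a C/EBPα peak than lost one, a direction that turned with a 5 kb window (386 lost, 315 gained) and without WT list 1 (444 lost, 355 gained). A gained peak stood at 299 genes (10.3% of the 2916 with a peak in both KO lists), a lost one at 140 (5.86% of the 2391 with a peak in both WT lists), and 2128 genes had a peak in every list. The other 2 splits of the 4 lists gave 11 and 147 genes and 12 and 87 genes, so another split gave as many genes as the 140 lost but not as many as the 299 gained. The widest gained gene-end peaks were at Cat, Dyrk1a, which encodes a protein kinase, Dclre1b, which encodes a nuclease that protects telomeres, Nr2c1, which encodes an orphan nuclear receptor, and Slc35f5, which encodes a solute carrier. Their mean width percentiles in the KO lists ran from 99.7 at Cat to 96.3 at Slc35f5. The widest lost ones were at Nat8f5, Acot5, which encodes a peroxisomal thioesterase of fatty acid metabolism, Myh4 and Ldhc, known for their expression in skeletal muscle and testis, and Pabpc4, which encodes a poly(A)-binding protein, with percentiles in the WT lists from 96.3 at Nat8f5 to 91.4 at Pabpc4. Leaving out KO list 2 gave 216 lost and 541 gained genes, and leaving out WT list 2 or KO list 1 gave 732 or 556 gained ones. A window of 500 bp gave 92 lost and 262 gained genes, the 16178 widest peaks of each list 93 lost and 486 gained, peaks at least as wide as the median 69 lost, and gene ends marked by H3K4me2 alone 47 lost.

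Plasma protein genes had C/EBPα peaks at their ends in WT and KO alike. Among 28 genes of plasma proteins, complement and coagulation, 26 had a gene-end peak in all 4 lists, Alb, Ttr, the fibrinogen genes Fga, Fgb and Fgg, and Serpinc1 among them. The count was 9 of 20 for lipid and lipoprotein genes such as Apob and Fasn, 8 of 21 for cytochrome P450 and xenobiotic genes such as Cyp3a25 and Ugt1a1, 6 of 12 for gluconeogenesis and glycogen genes such as Pck1 and G6pc, 5 of 14 for bile acid genes such as Abcb11 and Slc10a1, and 4 of 15 for urea cycle and amino acid genes such as Cps1. It was 11 of 19 for immediate early and regeneration genes such as Jun, Junb and Atf3, 8 of 15 for circadian clock genes such as Per1 and Dbp, 6 of 18 for housekeeping genes, 6 of 21 for growth restraint genes, 5 of 16 for hepatocyte transcription factors, 3 of 30 for cell cycle genes and 2 of 19 for SWI/SNF subunits. Of the remaining lists, macrophage, stellate cell, lymphocyte and neuronal genes had 0 such members, and fetal liver and endothelial genes 1 each (Gpc3 and Flt1). Apart from Alb, the members named here are examples chosen after their values were seen.

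No member of the 20 lists lost its gene-end peak, and 9 gained one. The gained members were Tdo2, an enzyme of tryptophan breakdown, Apoa2, an apolipoprotein of high-density lipoprotein, Cyp8b1, an enzyme of cholic acid synthesis, Xbp1, a transcription factor of the unfolded protein response, Smarcb1, a core SWI/SNF subunit, Mcm7, a subunit of the replicative helicase, the stress gene Gadd45b, and the housekeeping genes Gapdh and Tbp. The widest of them, at Gapdh, reached percentile 87.8 (chromosome 6, 125165282 to 125165958), and the narrowest, at Gadd45b, percentile 13.2 (chromosome 10, 80929935 to 80930269). In Fisher's exact tests with Benjamini-Hochberg adjustment, 0 of 20 lists passed in either direction. At an unadjusted p under 0.05 there was 1, the housekeeping genes, with 2 of 10 gained against 1.61% of other genes (Fisher's exact p = 0.0109, adjusted p = 0.217). Using only the 16178 widest peaks of each list, the housekeeping genes passed with 3 of 11 gained (Gapdh, Polr2a and Tbp; Fisher's exact test, adjusted p = 0.0470), and without KO list 1 the urea cycle and amino acid genes passed with 3 of 9 gained (Asl, Tat and Tdo2; adjusted p = 0.0402).

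The neighbourhoods of plasma protein, bile acid and urea cycle genes held few lost regions, in a count made after seeing the data over regions within 10 kb of a list gene. Near plasma protein genes 3 of 78 regions (3.85%) were lost, against 16.6% near other genes (Fisher's exact test, adjusted p = 0.0212). Near bile acid genes it was 2 of 57 (exact test, adjusted p = 0.0392) and near urea cycle and amino acid genes 0 of 32 (adjusted p = 0.0437), and no other list passed, hepatocyte lists such as gluconeogenesis (0 of 30, adjusted p = 0.0530) included. Other lists had low counts too, with 0 of 25 near growth restraint, 2 of 44 near clock and 4 of 50 near immediate early genes. Within strata of peak width the plasma protein, bile acid and urea cycle lists did not pass, with adjusted p values of 0.133, 0.133 and 0.283. The gene with the most lost regions was Scara5, which encodes a ferritin-binding scavenger receptor and was chosen after its values were seen. Within 10 kb of it, 7 of the 8 regions with a peak in both WT lists were lost (chromosome 14, 65715254 to 65759848). At these 7 regions H3K4me2 had no peak in any KO list and had peaks in 1 or 2 WT lists at 4 of them, and ARID1A had a peak at 2.

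**Figure D3:**
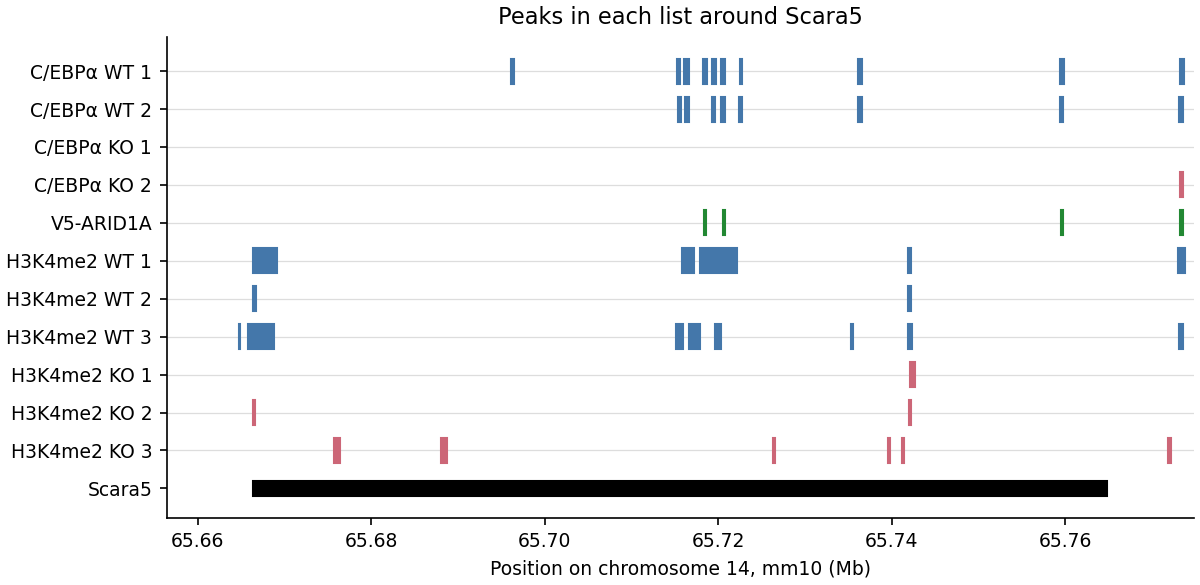
Peaks of each list within 10 kb of Scara5, by position on chromosome 14 of mm10 in Mb; boxes are peaks of the WT lists (blue), the KO lists (red) and the ARID1A list (green), and the black bar is the gene. Both C/EBPα WT lists hold the 7 lost regions between 65715254 and 65759848, where neither C/EBPα KO list has a peak.

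The second comparison asks where ARID1A sits in hepatocytes. Its widest peaks at genes with liver functions included 1 inside Ppara, a nuclear receptor of fatty acid oxidation (chromosome 15, 85771192 to 85772393), and 1 at 4081 bp from Gpt2, an alanine aminotransferase (chromosome 8, 85487975 to 85489017). Others of the 10 widest lay near 1600014C10Rik (3 peaks), Dnajc18, Mtss1, a regulator of the actin skeleton, and Kpna2, a nuclear import receptor. The 2 widest, between 39843000 and 39848872 on chromosome 17, are 105547 and 102579 bp from the nearest protein-coding gene, Esp38, and overlap Rn18s-rs5, a pseudogene of ribosomal RNA where all 4 C/EBPα lists also have peaks. Gene ends held 8.30% (7.59 to 9.04) of ARID1A peaks, against 3.62% of shuffled peaks, gene bodies 53.0% and the rest of the genome 38.7%. A window of 5 kb gave 25.5%, and keeping only the gene end marked by H3K4me2 in all 6 lists gave 4.99%.

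Hepatocyte genes were rich in ARID1A peaks. A peak stood at a gene end of 488 genes (2.23% of all protein-coding genes), and of 9 of 28 plasma protein genes (Crp, Hp and Ttr among them), 6 of 20 lipid genes (such as Ppara and Apob), 6 of 21 cytochrome P450 and xenobiotic genes (such as Ugt1a1, Cyp2c50 and Cyp3a25), 4 of 12 gluconeogenesis genes (such as Pck1, G6pc and Gys2), 4 of 15 urea cycle and amino acid genes (such as Tat, Hal and Tdo2) and 5 of 19 immediate early genes (such as Atf3, Stat3 and Egr1). These 6 lists passed Fisher's exact test with Benjamini-Hochberg adjustment over the 20 lists, with adjusted p from 1.20e-07 for plasma proteins to 9.14e-04 for the urea cycle list, in a test added after seeing the data. The remaining 14 lists did not pass. Those with a member at an ARID1A peak were bile acid (Nr0b2, Baat), transcription factor (Cebpb, Foxa2), clock (such as Bhlhe40), cell cycle (Ccnd1), SWI/SNF (Arid1b) and endothelial (Tie1) genes, and growth restraint, housekeeping, fetal, macrophage, stellate cell, biliary, lymphocyte and neuronal genes had none.

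ARID1A and C/EBPα peaks coincided. Of the ARID1A peaks, 70.3% (69.1 to 71.5) lay on a C/EBPα region present in both WT lists, against 0.563% of shuffled peaks and 0.786% in the highest of 100 shuffles. Shuffled peaks can fall anywhere on a chromosome, marked or not. The excess therefore does not separate a link with C/EBPα from marked chromatin shared by both. H3K4me2 peaks of the 3 WT lists covered 73.5%, 88.8% and 62.6% of ARID1A peaks, against 2.47%, 4.62% and 2.82% of shuffled peaks. Those of the 3 KO lists covered 41.7%, 82.9% and 53.0% of ARID1A peaks. The means of 75.0% ± 13.2 and 59.2% ± 21.3 (SD, n = 3) differed by less than the KO spread (exact permutation p = 0.3, with 0.1 the smallest possible).

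C/EBPα regions with an ARID1A peak were both lost and gained less than those without. Of 3991 such regions 194 (4.86%) were lost, against 2995 of 12538 (23.9%) without one, a log2 odds ratio of -2.62 (-2.83 to -2.40, Fisher's exact p = 6.08e-192). Of 3851 regions with an ARID1A peak and a C/EBPα peak in both KO lists 60 (1.56%) were gained, against 689 of 10371 (6.64%) without one, a log2 odds ratio of -2.16 (-2.54 to -1.77, Fisher's exact p = 5.53e-41). ARID1A peaks stood on 30.9% (30.0 to 31.7) of kept regions, 6.08% (5.28 to 6.97) of lost and 8.01% (6.17 to 10.19) of gained ones. At gene ends the contrast was smaller, 11 of 325 against 160 of 2041 lost (log2 odds ratio -1.22, Fisher's exact p = 0.00257), and within strata of peak width it was -0.71 (-1.63 to 0.21, p = 0.164). Of the 488 genes with an ARID1A gene-end peak, 337 had a C/EBPα peak in both WT lists, 12 lost it and 9 gained one, Tdo2 among the 9. These counts are by gene, and the ARID1A and C/EBPα peaks of a gene need not overlap. At Tdo2 the gained C/EBPα peak (chromosome 3, 81974603 to 81975276) and the ARID1A peak (81975702 to 81976015) lay apart. The ARID1A list is a single library, so the test compares these lists and has no replicate check.

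The third comparison asks where H3K4me2 changes without ARID1A. All 30 cell cycle genes had an H3K4me2 peak at a gene end in all 6 lists, as did 20 of 21 growth restraint genes, 18 of 19 SWI/SNF subunits, 25 of 28 plasma protein genes and 11 of 21 cytochrome P450 and xenobiotic genes. Of all protein-coding genes, 11166 were marked in every list, 16 were lost (marked in all 3 WT lists and no KO list) and 2 gained. The lost ones with the highest −log10 q percentiles were Capn8, which encodes a calpain protease (percentile 60.5), Nrbp1, Grin1, which encodes a subunit of a neuronal glutamate receptor, Mup1, which encodes a major urinary protein made in the liver and has near-identical copies in which short reads are hard to place, and Lcn2, which encodes an iron-sequestering protein of the acute phase (45.8). The gained ones were Alkal2, which encodes a receptor tyrosine kinase ligand (52.7), and 4930432M17Rik (36.5). Leaving out WT list 1, WT list 3, KO list 2 or KO list 3 gave 47, 33, 176 or 28 lost genes, and leaving out WT list 2, KO list 1, KO list 2 or KO list 3 gave 36, 112, 4 or 5 gained ones. Over all alternatives the counts ran from 4 to 176 lost and from 0 to 112 gained genes, the lowest with a 5 kb window and a stricter threshold.

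No fixed list passed for H3K4me2 in either direction. Grin1 was the only list member lost, which gave the neuronal genes 1 of 4 lost (Fisher's exact test, p = 0.00531, adjusted p = 0.106), the single list with an unadjusted p under 0.05, and no member was gained. Without WT list 1 the neuronal genes passed, with Grin1 and Nefl lost among 5 (Fisher's exact test, adjusted p = 0.00282). By 1-kb bins, 17521 were marked in all 6 lists, 663 were lost and 34 gained. Other splits of the 6 lists gave up to 4128 bins and 508 genes, against 697 bins and 18 genes for the split by genotype. Leaving out WT list 1, WT list 3 or KO list 2 gave 2208, 1737 or 5718 lost bins, and leaving out WT list 2 or any of the KO lists 1 to 3 gave 279, 1373, 56 or 91 gained bins. Counting any 1 bp of a bin gave 1436 lost and 58 gained bins, and a stricter threshold, lists of equal length and merged regions gave 6, 12 and 14 gained.

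KO list 3 stood apart from the other H3K4me2 lists. It held 175797 peaks with a median −log10 q of 1.14 and a median width of 429 bp, while medians in the other 5 lists were 2.42 to 4.75 and 634 to 918 bp. In KO list 3, 9.73% of peaks were at gene ends, against 23.0% to 47.5% in the other 5. The log2 ratio of KO to WT peak number was 0.81 with it (exact permutation p = 0.8, with 0.1 the smallest possible) and -0.29 without it, and -0.43 when only peaks above the pooled median −log10 q of 1.88 were counted. Covered length was 64.0 Mb ± 24.2 in WT and 72.0 Mb ± 39.0 in KO (SD, n = 3, exact permutation p = 0.9).

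The last comparison joins H3K4me2 to C/EBPα loss. Lost C/EBPα regions carried an H3K4me2 peak in 32.9%, 56.0% and 33.0% of cases in the WT lists and in 6.80%, 30.5% and 23.3% in the KO lists. The means were 40.6% ± 13.3 and 20.2% ± 12.2 (SD, n = 3), with every KO list below every WT list (exact permutation p = 0.1, the smallest possible; chance gives such a separation in 10% of cases). At kept regions the WT lists gave 73.3%, 87.6% and 68.3% (mean 76.4%) and the KO lists 49.3%, 82.5% and 61.0% (mean 64.3%, exact permutation p = 0.4, n = 3), and at gained regions 76.4% ± 7.32 and 71.7% ± 12.5 (exact permutation p = 0.6, n = 3). The KO mean was thus below the WT mean at kept and gained regions alike, by less at gained ones. Gene ends held 38.3% of gained, 17.7% of kept and 5.36% of lost regions, and the comparisons between these classes were not split by place. In a comparison added after seeing the data, the share at gained minus kept regions was 7.44 percentage points higher in KO than in WT, with every KO list above every WT list (exact permutation p = 0.1, n = 3, the smallest possible). It was 2.60 with the 24908 highest-ranked peaks of each list and 8.30 with a stricter threshold, where the lists of both genotypes overlapped (exact permutation p = 0.3 and 0.2), and 4.67 without H3K4me2 KO list 1. The same measure at lost regions minus kept regions was -8.23 percentage points (exact permutation p = 0.2, n = 3). With only peaks above the pooled median −log10 q it turned to 3.03, and with the 24908 highest-ranked peaks of each list to 1.13, so its direction depended on which H3K4me2 peaks were counted. Without H3K4me2 KO list 2 the difference was -4.27 and without C/EBPα WT list 1 it was -4.72.

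**Figure D4:**
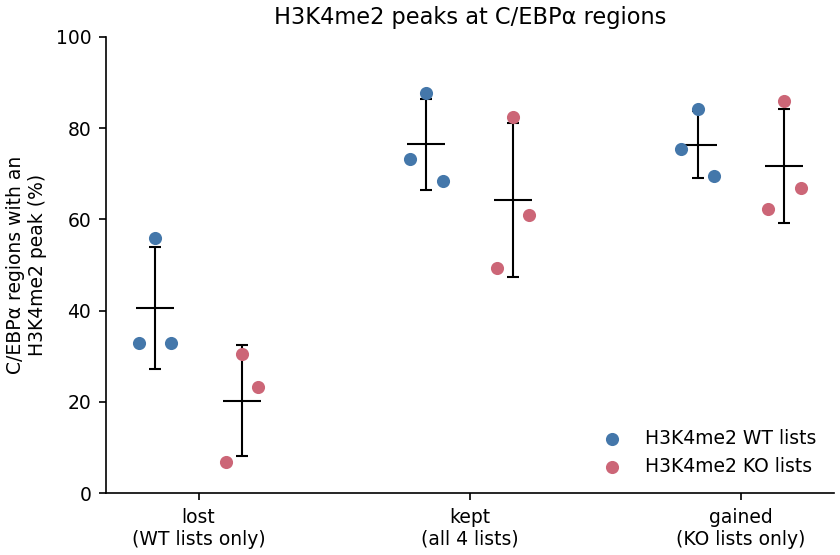
Percent of lost, kept and gained C/EBPα regions that overlap an H3K4me2 peak; each point is 1 of the 3 WT (blue) or 3 KO (red) H3K4me2 lists, and the black marks are the mean and SD. At lost regions the means are 40.6% in WT and 20.2% in KO, at kept regions 76.4% and 64.3%, and at gained regions 76.4% and 71.7%.

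Region by region, H3K4me2 was missing from the KO lists more at lost than at kept C/EBPα regions. Among regions with H3K4me2 in all 3 WT lists, 120 of 618 lost regions (19.4%) had H3K4me2 in no KO list, against 95 of 7019 kept regions (1.35%). The log2 odds ratio was 4.13 (3.72 to 4.54, Fisher's exact p = 1.01e-76), and splits of the 6 H3K4me2 lists that mix the genotypes gave up to 4.23. In the reverse direction, of regions with H3K4me2 in all 3 KO lists, 0 of 151 lost and 1 of 4729 kept ones had it in no WT list. At Cdh1, the gene of E-cadherin, chosen after its values were seen, 4 of 4 C/EBPα regions within 10 kb were lost and 2 of these had H3K4me2 in all 3 WT lists and no KO list. Of the 663 lost H3K4me2 bins 55 (8.30%, 6.31 to 10.7) contained a lost C/EBPα region, against 0.502% (0.403 to 0.618) of bins marked in all 6 lists and at most 4.55% in other splits. Gene ends held 11.3% of the lost bins, 59.9% of the bins marked in all 6 lists and 5.36% of lost C/EBPα regions. The contrast between bins was not split by place, so place may account for part of it. At Capn8, 4 of 4 C/EBPα regions within 10 kb were lost, and 0 of these had H3K4me2 in all 3 WT lists and no KO list. Counted by gene end, Capn8 had a lost H3K4me2 peak (chromosome 1, 182562724 to 182564180).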

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

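Of 157 values computed under alternatives for 18 results, 102 kept their direction and side of the threshold, or stayed close to the reported value, and 55 did not. Results with permutation or sign-flip tests, which cannot go below 0.05 here, were judged by direction alone. Of the 157, 116 were planned and 41 (wider peaks only, equal length by width, the H3K4me2-marked end only, regions within 10 kb, C/EBPα lists left out of the H3K4me2 comparison, and all those for H3K4me2 at gained C/EBPα regions) were chosen after seeing the data. The log2 odds of C/EBPα loss with an ARID1A peak stayed between -2.78 and -2.03, and the gene-end share of C/EBPα peaks was 4.63 to 6.91 percentage points higher in KO under all of their alternatives. The H3K4me2 share at gained minus kept C/EBPα regions stayed 2.60 to 9.46 percentage points higher in KO. The KO and WT lists overlapped in it with a stricter threshold (8.30, exact permutation p = 0.2) and with lists of equal length (2.60, p = 0.3). Where values moved, the cause was not tested, except that leaving a library out loosens the rule that all lists of a genotype share a feature, and equal length leaves fewer peaks in the longer lists. A stricter threshold turned the H3K4me2 peak number to -0.43 and H3K4me2 at lost C/EBPα regions to 3.03 percentage points, with 6 gained bins and 0 gained gene ends. H3K4me2 lists of equal length gave 1.13 for lost C/EBPα regions, 12 gained bins and 7 gained gene ends. Leaving out 1 library at a time gave 3781 to 7067 lost and 954 to 2363 gained C/EBPα regions, 179 to 444 lost and 355 to 732 gained C/EBPα gene ends, and 0 to 1 gene lists. For H3K4me2 it gave 727 to 5718 lost and 47 to 1373 gained bins, 17 to 176 lost and 2 to 112 gained gene ends, 0 to 1 gene lists, and a log2 peak number of -0.29 (without KO list 3) to 1.24. Counting any 1 bp of a bin gave 1436 lost and 58 gained bins, and merged regions gave 14 gained. A window of 500 bp gave 92 lost C/EBPα gene ends, 1 gained H3K4me2 gene end and 5.61% of ARID1A peaks at gene ends; 5 kb gave 386, 5 gained and 4 lost H3K4me2 gene ends, and 25.5%. Only peaks at least as wide as the median left 1216 lost regions, 69 lost gene ends and 59.8% of ARID1A peaks on C/EBPα regions. Equal length by width gave 1916 lost and 1549 gained regions, 93 lost and 486 gained gene ends and 1 gene list. The H3K4me2-marked end only, for the 10202 genes with exactly 1, gave 47 lost gene ends and 4.99% of ARID1A peaks. Regions within 10 kb gave 3 gene lists, and 0 within strata of width.

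Same-numbered libraries taken as pairs (a replicate block) gave -0.27 for the C/EBPα peak number (exact sign-flip p = 0.5), 5.40 for the gene-end share (p = 0.5), 0.39 for the H3K4me2 peak number (p = 1) -8.23 for lost regions (p = 0.25) and 7.44 for gained regions (p = 0.25), and changed no call. The labels give the numbers no meaning, and they were not taken to pair the samples because not every pair's correlation was over 0.1: the correlations of same-numbered lists were 0.0312 for C/EBPα and -0.0323, 0.313 and 0.178 for H3K4me2, where numbers 2 and 3 correlated best with their own number and number 1 with number 3. Thresholds on scores and equal length by score were not run for C/EBPα and ARID1A, whose lists hold no score, and the C/EBP motif was not run. Read depth is unknown, so how far it limits the peaks called in any list cannot be stated.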

Other observations

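The tests in this part were chosen only after the result was seen, except those of H3K4me2 at lost against kept C/EBPα regions by rank, by peak width and over splits of the lists. Endothelial and stellate cell markers carried H3K4me2 mostly in WT list 2 and KO list 2. Of 12 endothelial genes, among them Stab2, Tek and Cdh5, 11 had a gene-end peak in each of these 2 lists, against 4, 4, 2 and 5 in WT lists 1 and 3 and KO lists 1 and 3. The counts were 7 of 12 stellate cell and fibroblast genes in these 2 lists against 3, 3, 1 and 3 in the other 4. Macrophage genes gave 4 of 12 in these 2 lists against 1, 1, 2 and 4, biliary genes 5 of 10 against 5, 4, 2 and 4, and lymphocyte genes 4 of 10 against 2, 2, 2 and 5. Of the 1-kb bins marked in WT list 2 or KO list 2, 64.7% were marked in both, a larger share than for any other pair of the 6 lists. In both of these lists and in none of the other 4, 15590 bins were marked, while 40211 bins were marked in KO list 3 alone. All 14 bile acid genes were marked in all 6 lists.

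Several genes lost C/EBPα regions in number, counted within 10 kb of the gene; the genes named in this paragraph and the one before were chosen after their values were seen. Pde4b, a cyclic AMP phosphodiesterase, lost 6 of 9 regions present in both WT lists, and the tumour suppressor gene Fhit, Pard3b, Ptprg and Thada lost 5 each, of 7, 7, 13 and 10. Auts2, Fam222a and Macf1 lost 4 of 4. Pard3 and Foxn3 also lost 4 each, of 19 and 15, where 19.3% of all regions with a peak in both WT lists were lost. Such counts, that at Scara5 included, were not adjusted for gene length, so a long gene can rank high by holding more regions. Among these genes, length ran from 44.97 kb at Fam222a to 1611.97 kb at Fhit. Near cell cycle genes 7 of 22 regions (31.8%) were lost, 3 of 3 at Cdk1 and 1 each at Cdc6, Mcm5, Mcm7 and Mki67, against 16.5% near other genes (Fisher's exact test, adjusted p = 0.170, which does not pass). Gained regions were most numerous at Gbf1, Il4i1b and Serpinc1, the gene of antithrombin, with 3 each. With all fixed lists pooled, 0 of 103 genes lost a C/EBPα gene-end peak against 6.12% of other genes (Fisher's exact p = 0.00391), and 9 of 204 (4.41%) gained one against 1.59% (p = 0.00629). On the mitochondrial genome there were 2 H3K4me2 peaks in WT list 3 and 3 in KO list 3.

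Lost C/EBPα regions lay at gene ends less often than kept ones (5.36% against 17.7%), and gained regions more often (38.3%). Unequal list length is argued against by the WT list 1 and KO list 2, of 17733 and 17781 peaks: of the peaks that each lacks in the other, 5.73% and 25.1% were at gene ends, 19.4 percentage points apart. Peak width as the whole cause is argued against within strata of width, where the log2 odds at gene ends were -1.84 (-2.08 to -1.60) for loss and 1.57 (1.34 to 1.80) for gain. Width is only a rough measure of strength, so a better one could explain more. More background at active gene ends in the KO libraries stays open, because gained regions at gene ends had H3K4me2 in all 3 WT lists in 87.5% of cases (83.1 to 91.1), about the 84.8% of kept ones, as that source of peaks would give. A shift of C/EBPα occupancy that follows from the genotype may also stand behind the pattern, and the peak lists do not separate these 2.

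C/EBPα regions with an ARID1A peak kept their C/EBPα peak more often, and were also gained less (log2 odds -2.16, and -1.72 within strata of width). Gained regions have no C/EBPα peak in either WT list by definition, while 70.3% of ARID1A peaks lay on C/EBPα regions of both WT lists. Fewer ARID1A peaks at gained regions can follow from this alone, so the values for gain are no separate sign of constancy. Peak width as the whole cause is argued against over all regions, where within strata of width the log2 odds of loss were -2.03 (-2.25 to -1.81), against -2.62 without strata. At gene ends width stays open, since within strata the log2 odds there were -0.71 (-1.63 to 0.21). Among regions with H3K4me2 in all 3 WT lists, the log2 odds within strata of width were still -1.73 (-2.13 to -1.32). This argues against the presence of an H3K4me2 peak as the whole cause. Openness was not measured and the level of the mark was not held equal, so open chromatin shared by both proteins stays open. Width is a rough measure of strength, so a better one could explain more, and no biological explanation was tested beyond these overlaps.

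H3K4me2 was missing from all KO lists more often at lost than at kept C/EBPα regions, with log2 odds of 4.13. Weaker C/EBPα peaks at the lost regions, as measured by width, are argued against as the whole cause, since within strata of their width the log2 odds were 4.37 (3.91 to 4.83). Splits that mix the genotypes gave up to 4.53 within strata of width, so this value does not set the split by genotype apart. Lower sensitivity of the KO H3K4me2 lists cannot be told apart from a loss that follows the genotype: within strata of H3K4me2 rank the log2 odds were 3.48 (3.06 to 3.91), above the bound set beforehand, but 3 splits that mix the genotypes passed that bound too, up to 3.28, so the bound does not decide. The 10 splits of the 6 lists are too few for a share under 0.05; 2, the split by genotype included, gave log2 odds as large, the highest other being 4.23 from 1 lost region of 153.

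For the H3K4me2 counts, 4 of the 10 splits, the split by genotype included, gave as many bins as it did (697, highest other 4128) and 6, counted in the same way, gave as many genes (18, highest other 508), and 10 splits are too few for a share under 0.05. The split with 4128 bins set WT lists 1 and 2 and KO list 2 against the others. The split with 508 genes set WT list 2 and KO lists 2 and 3 against the others, and the cause was not tested for either split. In the first, the 3 lists named have median −log10 q of 4.75, 3.22 and 3.56 against at most 2.80 in the others, and in the second they cover 91.9, 85.6 and 102 Mb against at most 51.7 Mb. For gene lists all 10 splits gave the same count, 0 with 0 the highest other, so that count says nothing about chance.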
